A study of Homo sapiens with 8 samples.

How the data were processed

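Gene expression was measured by RNA sequencing in 8 libraries of SK-N-SH neuroblastoma cells: control cells with a GFP vector and the clone SD3.23, labelled as overexpressing MAML3, each untreated or with 1 µM RA, 2 libraries per group. Cells grew in medium with 8% serum. Libraries were made with the TruSeq RNA kit with 11 PCR cycles and sequenced on an Illumina HiSeq instrument as 51 bp reads. The submitters' processing notes name TopHat2 version 2.0.6, HTSeq with its version not given, and hg19. The deposited values were raw read counts per Ensembl gene, not normalized by the authors, with columns of gene start and end in bp on hg19. The counting mode, its strand setting and any filter were not given in the sources used here. A gene that overlaps another annotated gene, or has a nearly identical paralog, can therefore hold reads of both. Columns were matched to samples by the library names in the labels, and 0 count columns were left without a sample. The source field of the SD3.23 libraries with RA reads untreated, and the title and the treatment field, which read RA, were followed.

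The file listed 34750 genes, of which 4168 had 0 counts in all libraries. It gave a symbol for 21102 genes, a table of gene names gave one for 11598 more, and 2050 had none. Library totals ran from 12077581 to 14897349 counts, so 3 counts, the upper limit that a count of 0 allows, amounted to between 0.201 and 0.248 CPM in a library. The 10 most abundant genes took between 3.50% and 4.43% of the counts. Within groups, replicate libraries correlated with a Pearson coefficient of 0.995 across genes. The chi-square per gene against counting noise was 1.82, 1.31, 1.69 and 1.86 in the 4 groups, so the replicates differed by more than counting noise alone. Whether they were separate cultures was not stated in the sources used here.

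Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by the default of filterByExpr on the 4 groups (a minimum count of 10 and a minimum total of 15), which left 15298. Libraries were scaled by TMM, and the 8 libraries were fitted together as 4 group means with a quasi-likelihood model, which estimated a common dispersion of 0.000599. The 5 comparisons were RA against untreated in each kind of cell, SD3.23 against control without and with RA, and the difference between the RA responses. Each was tested with a two-sided quasi-likelihood F test, and p-values were adjusted by the method of Benjamini and Hochberg at 0.05 over all genes tested. Log2 fold changes used a prior count of 0.125. Where a group had 0 counts, the fold is a lower bound computed with 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with an exact 95% counting interval. The residuals of equally numbered libraries correlated between -0.0404 and 0.0286, which gave no sign that replicate numbers pair the libraries. Much of these residuals is counting error, so pairing is not excluded. No block was used in the reported values.

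The comparisons, tests, gene lists, rule for named genes and alternatives to be tried were fixed before the data were examined. The rule took MAML3, MAML1 and MAML2. It added the 8 genes with the largest increases and the 8 with the largest decreases for RA in control cells and for untreated SD3.23, and 5 and 5 for the other comparisons. These had to pass the test, reach 5 CPM in at least 1 of the compared groups, have libraries that did not overlap between the groups (not asked of the difference between responses) and carry a proper symbol. The rule also took up to 4 members of each list with the smallest adjusted p in each comparison. A few genes taken by the rule are not reported here. Of the 20 lists, 19 had at least 5 tested members: retinoid metabolism and targets, HOX and MEIS genes, adrenergic identity, mesenchymal identity, neuronal differentiation, Notch, Wnt targets, Hedgehog, DNA replication, mitosis, cell cycle inhibitors and p53 targets, MYC and ribosome biogenesis, the IGF system, collagens and matrix, immediate early genes, unfolded protein response and heat shock, interferon response, cholesterol synthesis, and Schwann and glial markers. The list of epithelial and blood markers had 3 tested members and no list test. Lists were tested with camera in limma on voom weights, with a preset correlation between genes of 0.01, and p-values were adjusted over the lists within each comparison. The HOXA and HOXB genes on the list were not tested, with at most 1 count in any group among those counted.

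The procedure was tested on simulated data with 15298 genes, of which 200 were changed, 50 at each fold. Simulated counts used the dispersions fitted to these libraries, so false calls from a larger true spread could not appear. Far more than 200 genes were called in the data, and that setting was not simulated. For RA in control cells the procedure recovered 34%, 76%, 72% and 98% of the changes of 1.2, 1.5, 2 and 4 fold. It made 4 false calls (2.78% of calls). For RA in SD3.23 it recovered 46%, 78%, 72% and 94% with 7 false calls, for untreated SD3.23 44%, 76%, 68% and 98% with 7, for SD3.23 under RA 46%, 74%, 74% and 96% with 6, and for the difference between responses 30%, 66%, 60% and 92% with 4. Of 20 simulated lists, the 1 that was changed was called and 0 others were, with the preset and with the estimated correlation. List members were simulated independently of one another, so false calls from correlated members could not appear. In the data the estimated correlation of the mitosis list was 0.32 in untreated SD3.23 against control. The alternatives were DESeq2 1.42.0, limma voom, RLE scaling, library size only, other filters, a test against a fold change of 1.5, fits of only the 4 libraries compared, the replicate number as a block, and leaving out each library in turn. For lists they were an estimated correlation and fry. An estimated correlation also leaves camera with the few residual degrees of freedom of 8 libraries in 4 groups. A call lost in that setting therefore need not come from correlation between members. A likelihood ratio test with an assumed coefficient of variation of 0.1 and a run without chromosome 18 were added after the data were seen.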

Results

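RNA from SK-N-SH cells, a human neuroblastoma line whose cultures hold neuroblast-like and substrate-adherent cells, was measured by RNA sequencing. Control cells carried a GFP vector, and the other cells were SD3.23, a clone that the labels describe as overexpressing MAML3, a coactivator of the Mastermind family that works with Notch receptors. Each kind of cell was left untreated or given 1 µM retinoic acid (RA), a derivative of vitamin A that drives neuroblastoma cells to differentiate. The 8 libraries fell into 4 groups of 2. The deposited values were raw read counts per gene. The untreated control libraries held 13116524 and 12121505 counts, and the control libraries with RA held 14897349 and 13141395. The untreated SD3.23 libraries held 12077581 and 14722464 counts, and the SD3.23 libraries with RA held 14420560 and 12325868. Of the 34750 genes listed, 15298 had enough counts to be tested. Values are CPM (read counts scaled by library size with TMM) as mean ± SD (n = 2), and log2 fold changes ± SE, with p-values from edgeR adjusted over all genes tested. The SE was not estimated directly: it is the absolute log2 fold change divided by the square root of the F statistic. It is approximate, and for large changes from few counts it can be smaller than counting error alone. Positions are on hg19. The labels number all control libraries in a separate series from all SD3.23 libraries, so a library batch and the kind of cell could not be told apart. A batch that acted alike on all libraries of one kind of cell would drop out of the RA responses and of the difference between them. The p-values measure only the spread between these libraries. Beyond counting noise this spread was small (a common biological coefficient of variation of 2.45%), and it can be technical.

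The labels name MAML3 as the gene that was raised in SD3.23, so its level was examined first. MAML3 (ENSG00000196782, chromosome 4, 140640419 to 141075338) stood at 70.6 ± 5.14 CPM in untreated control cells and 213 ± 0.425 CPM in untreated SD3.23 cells, a log2 difference of 1.60 ± 0.05 (adjusted p = 7.28e-51). Under RA it stood at 86.1 ± 0.251 CPM in control and 612 ± 44.4 CPM in SD3.23 cells, a log2 difference of 2.83 ± 0.04 (adjusted p = 6.91e-77). RA itself raised MAML3 by 0.29 ± 0.06 in control cells (adjusted p = 9.63e-06) and by 1.52 ± 0.04 in SD3.23 cells (adjusted p = 2.27e-56), and the responses differed by 1.23 ± 0.07 (adjusted p = 5.85e-30). The rise in control cells was no longer called with an assumed coefficient of variation of 0.1. MAML1, a related coactivator, was lower in SD3.23, with log2 differences of -0.27 ± 0.05 without RA (adjusted p = 3.16e-06) and -0.18 ± 0.05 with RA (adjusted p = 0.00180). The second of these calls was lost when the first control library with RA was left out (-0.12), and both were lost with the assumed coefficient of variation. The RA responses of MAML1 were -0.03 in control and 0.06 in SD3.23 cells, with a difference of 0.10, none past the test. MAML2, the remaining member of the family, had log2 fold changes of 0.00, 0.05, -0.36, -0.32 and 0.04 in the order of RA in control cells, RA in SD3.23, SD3.23 without RA, SD3.23 with RA and the difference of the responses, none past the test. Scaling by library size only turned the response of MAML2 in control cells to -0.02. MAML3 overlaps MGST2, and MAML1 overlaps LTC4S; the strand used in counting was not stated, so their counts can hold reads of these neighbours.

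**Figure D1:**
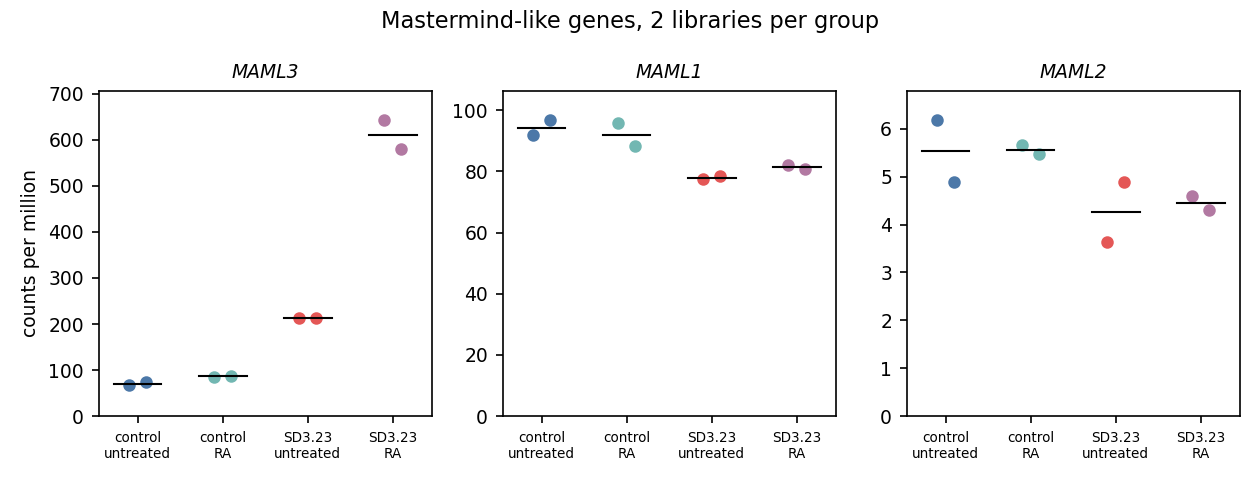
CPM of MAML3, MAML1 and MAML2 in each of the 8 libraries (points), with the group mean (line), for control and SD3.23 cells without and with RA, on linear axes that start at 0. MAML3 means ran from 70.6 in untreated control cells to 612 in SD3.23 cells with RA.

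The first comparison asked what RA changed in control cells. The RA-degrading CYP26 genes and the receptor genes NTRK2 and RET rose, and the growth gene MYC fell. CYP26A1 (ENSG00000095596, chromosome 10, 94833232 to 94837647), an enzyme that degrades RA, went from 2 to 6924 counts over the group, a ratio of 3116-fold (95% counting interval 862 to 25736). Its relative CYP26B1 (ENSG00000003137, chromosome 2, 72356367 to 72375167) rose from 0.778 ± 0.179 to 1263 ± 1.72 CPM, a log2 fold change of 10.64 ± 0.09 (adjusted p = 9.42e-102). NTRK2, the receptor for brain-derived neurotrophic factor, rose from 1.45 ± 0.134 to 353 ± 3.59 CPM (7.92 ± 0.09), and RET, the receptor for glial-cell-derived neurotrophic factor, from 70.3 ± 0.193 to 2293 ± 4.54 CPM (5.03 ± 0.05). MYC fell from 287 ± 19.9 to 97.9 ± 1.47 CPM (-1.55 ± 0.04, adjusted p = 7.38e-54).

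By fitted value, which is uncertain where a group had 0 counts, the 8 largest increases were completed by NR0B1, an orphan nuclear receptor (at least 159-fold higher, 0 against 531 counts), and CRYGC, a lens crystallin (at least 63.0-fold higher, 0 against 210 counts). The others were CALCA, which encodes calcitonin and its related peptide (8.20), TGM2, a transglutaminase (7.29), and CCBE1, a secreted factor of lymph vessel growth (7.25). Large decreases were those of ADAMTS17, a secreted protease (-4.40), RASD2, a small GTPase (-3.72), C1orf173 (-3.35), the imprinted gene RTL1 (-3.30), the transcription factors INSM2 (-3.26) and DRGX (-3.09), and FAT3, a large cadherin (-3.07). These intervals and bounds cover counting error only, and a bound takes 3 counts over the group in place of 0. CALCA lies beside its paralog CALCB and overlaps it, and ADAMTS17 overlaps unnamed transcripts, so their counts can be shared.

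Of 17 tested members of the retinoid list, 12 rose and 1 fell (camera adjusted p = 4.88e-14, and adjusted p = 0.0105 with an estimated correlation); besides the CYP26 genes and TGM2, they included the RA-binding protein CRABP2 (4.95). HOX and MEIS genes, which set position along the body axis, rose in 15 of 18 cases and fell in 0 (camera adjusted p = 1.34e-20, and adjusted p = 0.00913 with an estimated correlation), with HOXD8 at 2.94, HOXD4 at 2.67 and HOXD9 at 2.64; HOXD genes overlap one another or their antisense transcripts. Adrenergic genes, the markers of sympathetic neuroblasts, rose in 7 and fell in 14 of 23 cases (camera adjusted p = 3.76e-07, and adjusted p = 0.132 with an estimated correlation), and the noradrenaline-making enzyme DBH (-2.05), DLK1 (-2.08) and the noradrenaline transporter SLC6A2 (-1.12) were among those that fell. MYC and ribosome biogenesis genes fell in 22 of 23 cases (camera adjusted p = 1.88e-14, and adjusted p = 0.0640 with an estimated correlation), among them MTHFD2 (-0.41), NOP56 (-0.34) and NPM1 (-0.31). Cell cycle inhibitors and p53 targets rose in 9 and fell in 3 of 19 cases (camera adjusted p = 0.0130, and adjusted p = 0.132 with an estimated correlation), led by BTG2 (1.51), CDKN1B (0.57), TP53INP1 (0.43) and CDKN1A (0.37). Cholesterol synthesis genes rose in 10 and fell in 1 of 17 cases (camera adjusted p = 9.78e-05, and adjusted p = 0.153 with an estimated correlation), among those that rose INSIG1 (0.94), STARD4 (0.60) and FDFT1 (0.37). In the IGF system, 2 of 15 members rose and 5 fell (camera adjusted p = 0.0153, and adjusted p = 0.132 with an estimated correlation); the binding proteins IGFBP5 (-1.82) and IGFBP4 (-0.96) fell, while IGFBP6 (2.14) rose. Schwann and glial markers, which stand for another cell type, fell in 2 of 7 cases and rose in 0 (camera adjusted p = 0.0185, and adjusted p = 0.209 with an estimated correlation), namely PMP22 (-1.44) and MITF (-0.67).

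Camera did not call the remaining lists. Mesenchymal markers rose in 5 and fell in 4 of 14 cases (adjusted p = 0.379), with NOTCH2 at 1.92, VIM at -1.22, FOSL2 at -1.49 and NES at 0.70. Neuronal genes rose in 7 and fell in 14 of 28 cases (adjusted p = 0.521), with a median log2 fold change of -0.12. NEFM, a neurofilament (1.31), and the granule protein SCG2 (0.93) rose. By at least 2-fold, 3 neuronal genes rose and 3 fell. Notch genes rose in 4 and fell in 8 of 17 cases (adjusted p = 0.966), and JAG1 (2.83), a ligand, HES1 (1.89) and HEY1 (1.30), both targets, rose, while DNER (-1.10) fell. Wnt targets rose in 5 and fell in 6 of 14 cases (adjusted p = 0.538), with the inhibitor DKK2 at 3.75, TCF7 at 0.52 and CCND1 at -0.33. Hedgehog genes rose in 1 and fell in 4 of 10 cases (adjusted p = 0.289): PTCH1 (1.15) against CDON (-1.22) and BOC (-1.26). DNA replication genes fell in 7 of 25 cases and rose in 0 (adjusted p = 0.118), MCM5 at -0.26 and MCM7 at -0.22, and mitosis genes rose in 1 and fell in 5 of 26 cases (adjusted p = 0.289), CENPF at -0.25. Matrix genes rose in 8 and fell in 8 of 23 cases (adjusted p = 0.796), with FN1 at 1.83, COL3A1 at 1.15, FBN1 at -1.06 and COL4A2 at -0.85. Immediate early genes rose in 2 and fell in 1 of 11 cases (adjusted p = 0.538), JUNB at 0.54. Unfolded protein and heat shock genes rose in 4 and fell in 2 of 15 cases (adjusted p = 0.538), DNAJB1 at 0.32. Interferon genes rose in 5 and fell in 4 of 16 cases (adjusted p = 0.704), with IRF9 at 1.58, OAS3 at -1.48 and OAS1 at -2.26. Of the epithelial and blood markers, only 3 had enough counts, too few for a list test, and none passed: CD14 -0.80, EPCAM -0.62 and KRT19 -0.84.

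In all, 4780 genes changed, 2288 higher and 2492 lower, and 448 rose and 321 fell by at least 2-fold (edgeR quasi-likelihood test). Scaled by library size only, the split was 2064 higher and 2801 lower, and with RLE size factors 2348 and 2390. The larger side turned with DESeq2 (1408 and 1357) and with the test against a fold change of 1.5 (441 and 291). It also turned with the filter on a mean of at least 1 CPM (2356 and 2326) and with only the 4 libraries compared (2514 and 2362). The assumed coefficient of variation of 0.1 (824 and 731) and leaving out the second SD3.23 library with RA turned it too. Of the 8 lists called, 2 held with an estimated correlation. Adjusted over the list alone, the counts were the same except for 6 higher among mesenchymal, 9 higher and 15 lower among neuronal, 9 lower among Notch, 6 lower among DNA replication and 3 lower among unfolded protein genes. Median, mean and test differed in sign for the mesenchymal, neuronal, Notch, Wnt, immediate early and interferon lists. DESeq2 called 2765 genes, a test against a fold change of 1.5 called 732, and an assumed coefficient of variation of 0.1 left 1555 calls and ended 24 of the 86 calls among the genes named by rule. Of those mentioned here, they were CDKN1A, FDFT1, MTHFD2, NOP56, NPM1, CCND1, CENPF, DNAJB1, MCM5 and MCM7.

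The second comparison asked what RA changed in SD3.23. The degrading enzymes CYP26B1 (0.684 ± 0.20 to 245 ± 14.1 CPM, 8.50 ± 0.11) and CYP26A1 (0.827 ± 0.114 to 192 ± 10.7 CPM, 7.86 ± 0.11) had the largest increases among genes of at least 5 CPM in either group (adjusted p = 1.74e-83 and 5.20e-80). One label field of the SD3.23 libraries with RA reads untreated while their title and treatment field read RA; CYP26A1 stood at 192 CPM in them. MYC fell from 132 ± 1.97 to 37.0 ± 1.89 CPM (-1.84 ± 0.06, adjusted p = 9.46e-50). EGR1, an immediate early transcription factor, rose from 2.52 ± 0.874 to 23.8 ± 0.171 CPM (3.27 ± 0.15), and NTRK2 rose from 5.15 ± 0.656 to 63.7 ± 4.75 CPM (3.64 ± 0.10). The other large increases were in MAGEB3, a cancer-testis gene of the X chromosome (6.57), NR0B1 (6.18) and DKK2 (4.08). The other large decreases were in ADAMTS17 (-2.20), cardiac troponin T, TNNT2 (-2.17), the kainate receptor subunit GRIK3 (-1.80) and the water channel AQP10 (-1.80).

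Retinoid genes rose in 12 and fell in 2 of 17 cases (camera adjusted p = 1.32e-13, and adjusted p = 0.0210 with an estimated correlation), with CRABP2 at 2.49 and the receptor RARB at 1.88. HOX and MEIS genes rose in 11 and fell in 2 of 18 cases (camera adjusted p = 1.09e-07, and adjusted p = 0.0347 with an estimated correlation), HOXD10 at 0.99, HOXD8 at 0.96 and HOXD13 at 0.76. Wnt targets rose in 9 and fell in 3 of 14 cases (camera adjusted p = 3.81e-07, and adjusted p = 0.0369 with an estimated correlation), among them DKK1 (1.63), the receptor FZD7 (1.21) and cyclin D1, CCND1 (0.86). DNA replication genes rose in 15 of 25 cases and fell in 0 (camera adjusted p = 1.03e-05, and adjusted p = 0.116 with an estimated correlation), with the loading factor CDC6 at 0.42 and the helicase subunit MCM3 at 0.24. MYC and ribosome biogenesis genes fell in 18 of 23 cases and rose in 0 (camera adjusted p = 1.92e-13, and adjusted p = 0.0524 with an estimated correlation), with the polyamine enzymes ODC1 at -0.68 and SRM at -0.53. Adrenergic genes rose in 4 and fell in 10 of 23 cases (camera adjusted p = 2.10e-04, and adjusted p = 0.186 with an estimated correlation), DLK1 at -0.57 and GATA3 at -0.52. Neuronal genes rose in 10 and fell in 6 of 28 cases (camera adjusted p = 8.18e-05, and adjusted p = 0.0901 with an estimated correlation), with SCG2 at 1.66, NEFM at 1.52 and VGF at 1.27. Mesenchymal markers rose in 5 and fell in 1 of 14 cases (camera adjusted p = 0.0473, and adjusted p = 0.186 with an estimated correlation), MAFF at 1.18 and YAP1 at 0.57 against FOSL2 at -0.68. This call was lost without the second untreated (0.112) or the second RA library of SD3.23 (0.0561). Cholesterol genes rose in 7 and fell in 1 of 17 cases (camera adjusted p = 0.0473, and adjusted p = 0.357 with an estimated correlation), STARD4 at 0.33; this call was lost on leaving out any 1 of 6 libraries, with adjusted p-values from 0.0501 to 0.123.

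Notch genes rose in 5 and fell in 5 of 17 cases (adjusted p = 0.855), HEY1 (2.70) and JAG1 (0.79) against LFNG (-1.06) and DLL3 (-1.01). Hedgehog genes rose in 1 and fell in 3 of 10 cases (adjusted p = 0.0953), GLI2 at -0.52 and CDON at -0.52. Cell cycle inhibitors and p53 targets rose in 2 and fell in 5 of 19 cases (adjusted p = 0.126), with CDKN1C at -1.11, BBC3 at -0.89 and CDKN1A at -0.27. Mitosis genes rose in 4 and fell in 3 of 26 cases (adjusted p = 0.665), or 3 and 5 when scaled by library size only, and MKI67 was at 0.22. Members of the IGF system rose in 4 and fell in 6 of 15 cases (adjusted p = 0.321), with IGFBP5 at -1.11 and IGFBP4 at -0.80. Matrix genes rose in 6 and fell in 10 of 23 cases (adjusted p = 0.665), COL3A1 at 1.72 and COL11A1 at 1.23 against COL6A1 at -0.50. Immediate early genes rose in 2 of 11 cases (adjusted p = 0.0671) and unfolded protein genes in 2 of 15 (adjusted p = 0.485, ATF4 at 0.19), with 0 falling in either list. Interferon genes fell in 2 of 16 cases and rose in 0 (adjusted p = 0.665), OAS3 at -0.22. Schwann and glial markers rose in 2 and fell in 2 of 7 cases (adjusted p = 0.665), PMP22 at -0.54. The epithelial and blood markers did not pass, with CD14 at 0.80, KRT19 at -0.22 and EPCAM at 0.18.

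RA changed 4036 genes in SD3.23, 2065 higher and 1971 lower, with 254 rising and 118 falling by at least 2-fold. Scaled by library size only, the split was 1648 higher and 2458 lower; with RLE size factors it was 2307 and 1746, and with DESeq2 1171 and 797. Adjusted over the list alone, 10 Wnt, 17 DNA replication, 11 neuronal and 6 mesenchymal genes were higher, 3 retinoid, 3 HOX and MEIS and 19 MYC and ribosome biogenesis genes were lower, mitosis gave 5 higher and 4 lower, interferon 1 lower, and the rest were as above. Of the 9 lists called, 3 held with an estimated correlation. Median, mean and test differed in sign for the IGF, matrix, interferon and Schwann lists. DESeq2 called 1968 genes, the test against a fold change of 1.5 called 341, and the assumed coefficient of variation left 828 calls and ended 23 of 77 calls among genes named by rule, here those of CDC6, MCM3, STARD4, ATF4, CDKN1A, MKI67 and OAS3.

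The third comparison asked whether the RA responses of control and SD3.23 cells had a similar size. Of 2288 genes that rose in control cells, 1015 also rose in SD3.23, against 309 for independent lists of these lengths, and of 2492 that fell, 1042 also fell, against 321. Over the 6524 genes called in either, the median absolute log2 fold change was 0.26 in control and 0.21 in SD3.23 cells, a ratio of 0.812 (0.867 and 0.806 when computed from the libraries numbered 1 and 2 alone). The genes called in control cells had medians of 0.34 and 0.19, and those called in SD3.23 had 0.22 and 0.29, so each selection favoured the cells it was made in. Among 2292 genes called in both, the medians were 0.38 and 0.33, and 2057 genes had the same sign. Across all tested genes, which are not independent replicates, the ratio was 0.899, the response was larger in control cells for 54.6%, and the responses correlated with a Pearson coefficient of 0.522 and a Spearman coefficient of 0.411.

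**Figure D2:**
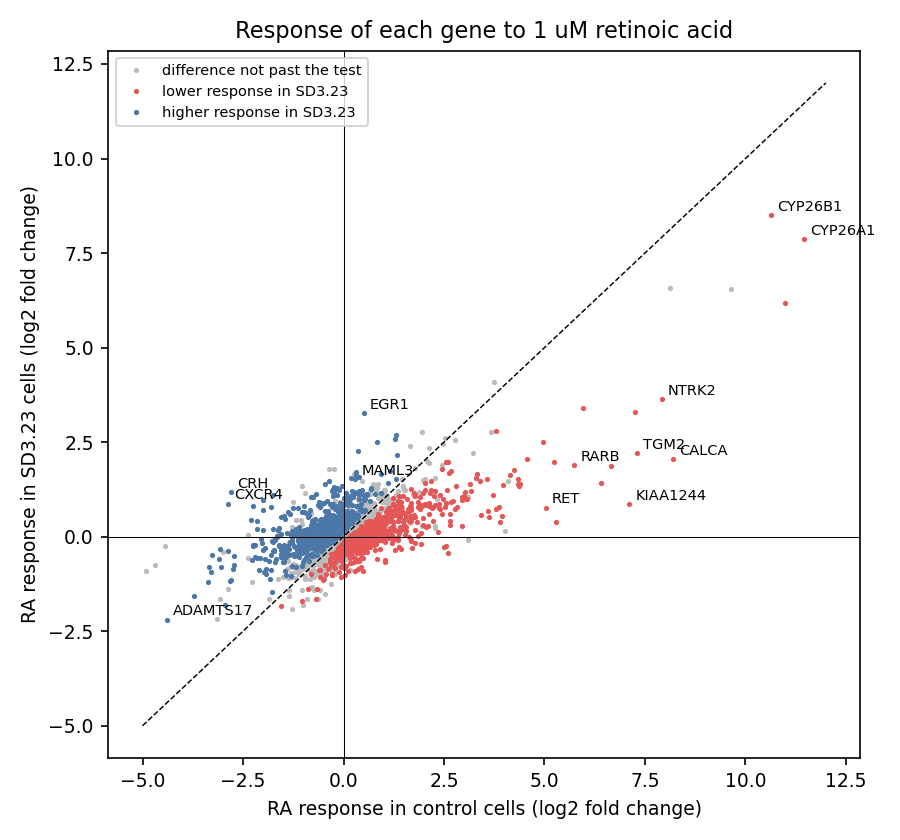
Log2 fold change with RA in control cells (x axis) against SD3.23 cells (y axis), 1 point per gene with at least 5 CPM in at least 1 group; the dashed line marks equal responses. Colours mark the test of the difference between the responses, which over all tested genes called 1130 more positive (blue) and 1049 more negative (red) in SD3.23.

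The difference between the RA responses was then tested gene by gene, as the response in SD3.23 minus the response in control cells. Several genes that RA induced strongly in control cells had smaller responses in SD3.23. NTRK2 rose from 1.45 to 353 CPM in control and from 5.15 to 63.7 CPM in SD3.23 cells, a difference of -4.27 ± 0.23 (adjusted p = 2.89e-30). RET went from 70.3 to 2293 CPM and from 1569 to 2669 CPM (-4.26 ± 0.06, adjusted p = 4.70e-80). MYCN, the oncogene of high-risk neuroblastoma, moved from 3.81 to 0.826 CPM in control and from 16.3 to 14.1 CPM in SD3.23 cells (1.98 ± 0.32, adjusted p = 3.98e-07). The largest positive differences were those of CRH, corticotropin-releasing hormone (3.98), the chemokine receptor CXCR4 (3.75), PCDH10, a protocadherin (3.05), TFPI2, a protease inhibitor (2.97), and TMEM229A (2.86). The largest negative differences were those of KIAA1244 (-6.25), CALCA (-6.15), TGM2 (-5.09), UBL4B (-4.99) and SNCAIP, which encodes a partner of alpha-synuclein (-4.90). UBL4B (adjusted p = 0.00916) had 0 counts in untreated control cells, so its fitted value is no bound, and its call was lost with DESeq2 (0.0696) and without the first (0.0974) or second (0.0778) untreated control library.

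HOX and MEIS genes had a more positive response in SD3.23 in 1 and a more negative one in 14 of 18 cases (camera adjusted p = 6.89e-17, and adjusted p = 0.0135 with an estimated correlation), with HOXD9 at -2.06, HOXD8 at -1.98 and HOXD10 at -1.49. Retinoid genes were more positive in 1 and more negative in 10 of 17 cases (camera adjusted p = 9.36e-10, and adjusted p = 0.0211 with an estimated correlation), with RARB at -3.85 and CRABP2 at -2.46. Cell cycle inhibitors and p53 targets were more negative in 9 of 19 cases and more positive in 0 (camera adjusted p = 1.86e-06, and adjusted p = 0.0345 with an estimated correlation), BTG2 at -1.21, CDKN1A at -0.64, CDKN1B at -0.59 and TP53INP1 at -0.49. DNA replication genes were more positive in 13 of 25 cases and more negative in 0 (camera adjusted p = 1.13e-08, and adjusted p = 0.0792 with an estimated correlation), MCM5 at 0.43 and MCM3 at 0.36. Adrenergic genes were more positive in 10 and more negative in 4 of 23 cases (camera adjusted p = 9.63e-07, and adjusted p = 0.102 with an estimated correlation), DBH at 1.98, DLK1 at 1.51 and SLC6A2 at 1.11. Wnt targets were more positive in 6 and more negative in 1 of 14 cases (camera adjusted p = 4.06e-05, and adjusted p = 0.0994 with an estimated correlation), DKK1 at 1.31, the stem cell receptor LGR5 at 1.26 and CCND1 at 1.19. Neuronal genes were more positive in 12 and more negative in 3 of 28 cases (camera adjusted p = 0.00444, and adjusted p = 0.132 with an estimated correlation), VGF at 1.49 and NEFL at 0.93 against NTRK2 and RET; the median was 0.10 and the mean -0.08. The IGF system was more positive in 5 and more negative in 1 of 15 cases (camera adjusted p = 0.00444, and adjusted p = 0.0994 with an estimated correlation), IRS2 at 0.98 and IGFBP5 at 0.71. Cholesterol genes were more negative in 7 of 17 cases and more positive in 0 (camera adjusted p = 0.00444, and adjusted p = 0.239 with an estimated correlation), INSIG1 at -1.03. Schwann and glial markers were more positive in 2 of 7 cases and more negative in 0 (camera adjusted p = 0.00444, and adjusted p = 0.132 with an estimated correlation), the neurotrophin receptor NGFR at 1.17 and PMP22 at 0.90.

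Lists that camera did not call were mesenchymal (4 more positive and 3 more negative of 14, adjusted p = 0.606), Notch (3 and 2 of 17, 0.606), Hedgehog (1 and 2 of 10, 0.929) and mitosis (5 and 1 of 26, 0.0564). VIM was at 1.27, NOTCH2 at -1.82, HEY1 at 1.40, JAG1 at -2.04, DNER at 1.22 and PTCH1 at -0.91. MYC and ribosome biogenesis genes had 4 more positive and 3 more negative of 23 (adjusted p = 0.262), matrix genes 7 and 3 of 23 (0.606), immediate early genes 3 and 1 of 11 (0.166), unfolded protein genes 2 and 1 of 15 (0.929) and interferon genes 3 and 3 of 16 (0.475). FN1 was at -1.44, LAMA4 at -1.08, FBN1 at 0.94, EGR1 at 2.77, OAS1 at 2.05 and OAS3 at 1.27. CD14 (1.60), EPCAM (0.80) and KRT19 (0.62) did not pass.

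The responses differed for 2179 genes, 1130 more positive and 1049 more negative in SD3.23, of which 238 and 216 differed by at least 2-fold. Of the 10 lists called, 3 held with an estimated correlation. Adjusted over the list alone, 11 retinoid genes, 10 cell cycle inhibitors and 8 cholesterol genes were more negative, and 18 DNA replication, 7 IGF, 5 mesenchymal and 3 Schwann genes were more positive. Adrenergic genes then gave 12 and 5, neuronal genes 13 and 4 and matrix genes 7 and 7, and the rest were as above. Median, mean and test also differed in sign for the Hedgehog, unfolded protein and interferon lists. DESeq2 called 1061 genes, the test against a fold change of 1.5 called 354, and the assumed coefficient of variation left 541 calls and ended 31 of 82 calls among genes named by rule, here those of CDKN1A, CDKN1B, TP53INP1, MCM3 and MCM5.

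**Figure D3:**
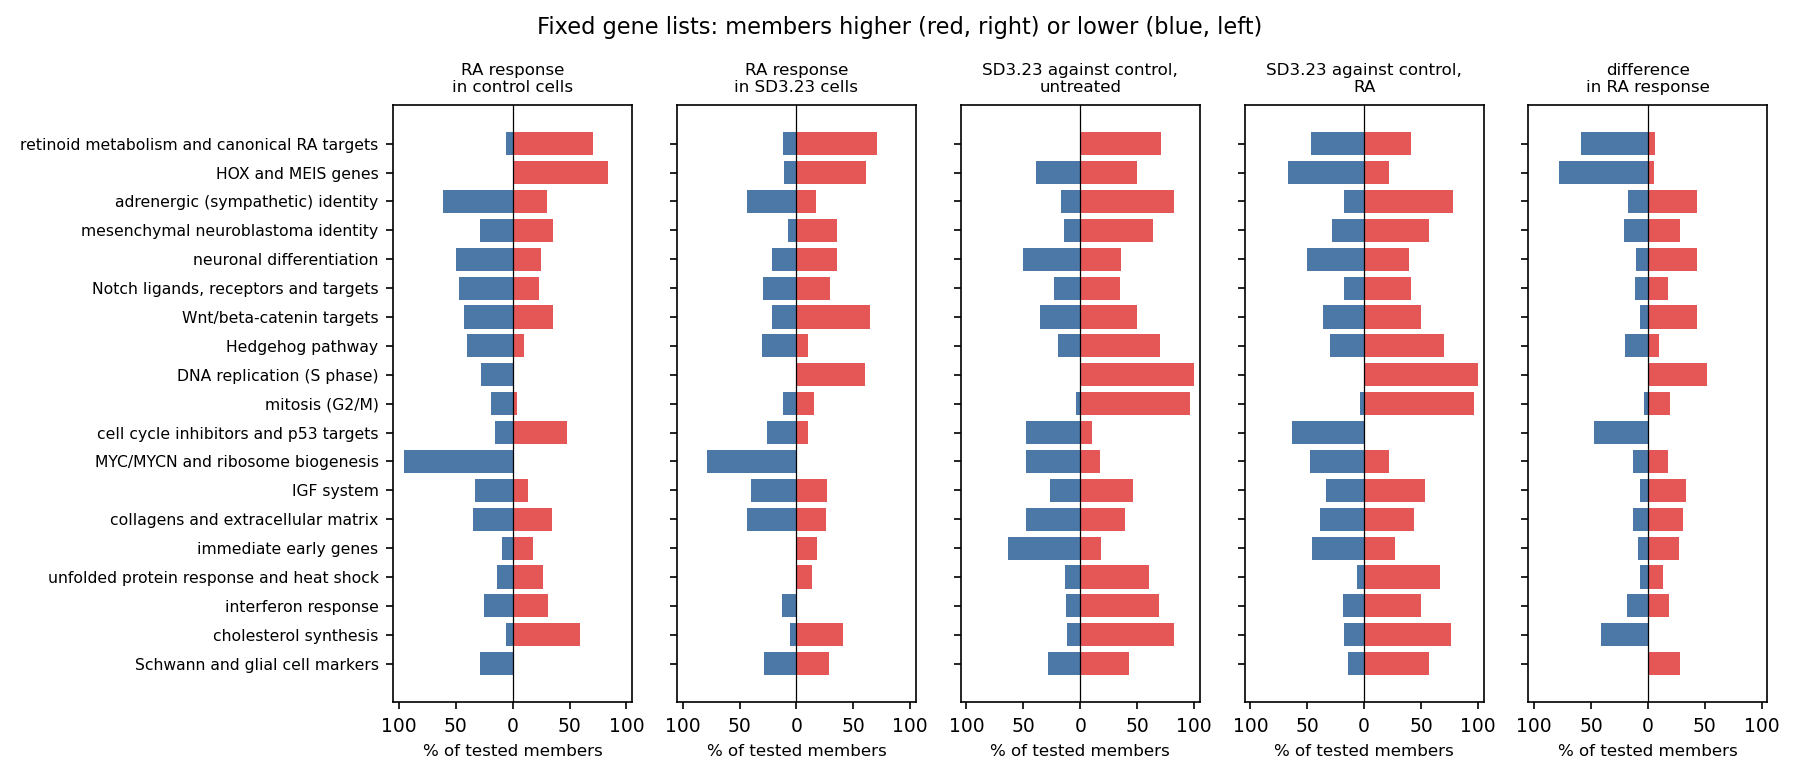
Percent of the tested members of each of 19 gene lists that were called higher (red bars, to the right of 0) or lower (blue bars, to the left), in 5 panels for the 5 comparisons. In the HOX and MEIS list 15 of 18 members rose with RA in control cells, 11 of 18 rose in SD3.23, and 14 of 18 had a more negative response in SD3.23.

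The next comparison asked how untreated SD3.23 differed from untreated control cells. A clone can differ from its parent line in more than the gene it is labelled as overexpressing. The growth factor gene IGF2, several sympathetic marker genes and most cell division genes were higher in SD3.23. IGF2 (ENSG00000167244, chromosome 11, 2150342 to 2182439), which encodes an insulin-like growth factor, stood at 3.64 ± 1.58 CPM in control and 3355 ± 54.9 CPM in SD3.23 cells (9.83 ± 0.07, adjusted p = 2.14e-104). DLK1, a non-canonical Notch ligand, stood at 123 ± 2.08 and 2822 ± 26.6 CPM (4.51 ± 0.04, adjusted p = 1.62e-94), and DBH at 195 ± 3.32 and 3201 ± 40.7 CPM (4.04 ± 0.04). MYCN stood at 3.81 ± 0.482 and 16.3 ± 0.226 CPM (2.10 ± 0.15), while MYC was lower, at 287 ± 19.9 and 132 ± 1.97 CPM (-1.12 ± 0.04). DNA replication genes were higher in 25 of 25 cases and mitosis genes in 25 of 26.

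Among genes close to absent in control cells, TMEM200A was at least 374-fold higher, the noncoding RNA LINC02382 at least 283-fold, MOXD1 at least 255-fold and PRUNE2 at least 246-fold, each from 0 counts in control. The chemokine receptor CXCR7 was at least 162-fold higher and the transcription factor LMX1B at least 79.7-fold higher, also from 0. CD177, a neutrophil surface protein, had a ratio of 2325-fold (95% counting interval 643 to 19200.5), and CMKLR1, the chemerin receptor, one of 1260.0-fold (95% counting interval 348 to 10409.7). Lower in SD3.23 were cancer-testis genes of the X chromosome: MAGEA6 by 958-fold (95% counting interval 171 to 37874), MAGEA3 by 436-fold (95% counting interval 120.3 to 3605), CSAG1 by 148-fold (95% counting interval 50.3 to 720.4) and MAGEA12 at a log2 fold change of -6.72. Also lower were GLT1D1 by 175-fold (95% counting interval 48.0 to 1448), KIAA2022 by 186-fold (95% counting interval 32.9 to 7381), FAIM3 by 171-fold (95% counting interval 30.3 to 6794), and the nuclear receptor RORB at -6.62. MAGEA3 and MAGEA6 are nearly identical in sequence, so reads can be assigned to either. IGF2 overlaps INS and IGF2-AS, PRUNE2 overlaps PCA3 and MAGEA12 overlaps CSAG4.

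Adrenergic genes were higher in 19 and lower in 4 of 23 cases (camera adjusted p = 1.57e-13, and adjusted p = 0.0921 with an estimated correlation), with the granin CHGA at 3.92 and SLC6A2 at 1.57 besides DLK1 and DBH. DNA replication genes (camera adjusted p = 2.45e-09, and adjusted p = 0.0921 with an estimated correlation) included RRM2 (1.08), MCM3 (0.63), POLE (0.60) and PCNA (0.48). Mitosis genes, 25 higher and 1 lower (camera adjusted p = 1.38e-11, and adjusted p = 0.146 with an estimated correlation), included AURKB (1.02), CCNA2 (0.77), CDK1 (0.69) and BUB1 (0.69). Retinoid genes were higher in 12 of 17 cases and lower in 0 (camera adjusted p = 1.52e-05, and adjusted p = 0.0921 with an estimated correlation), among them CRABP2 (4.89), RARB (3.06), ALDH1A3 (1.57) and STRA6 (0.86). Cholesterol genes were higher in 14 and lower in 2 of 17 cases (camera adjusted p = 1.08e-07, and adjusted p = 0.114 with an estimated correlation), MVK at 1.58, DHCR7 at 1.11 and LSS at 1.01. Unfolded protein and heat shock genes were higher in 9 and lower in 2 of 15 cases (camera adjusted p = 0.0127, and adjusted p = 0.141 with an estimated correlation), SDF2L1 at 1.51, the chaperone HSPA5 at 1.01 and DNAJB1 at 0.81. Mesenchymal markers were higher in 9 and lower in 2 of 14 cases (camera adjusted p = 0.0284, and adjusted p = 0.146 with an estimated correlation), FOSL2 at 0.87 and VIM at 0.42 against TWIST1 at -0.61. Neuronal genes were higher in 10 and lower in 14 of 28 cases (camera adjusted p = 0.0184, and adjusted p = 0.169 with an estimated correlation), RET at 4.48 against NTRK3 at -4.22, DCX at -4.18 and NCAM1 at -1.37. Cell cycle inhibitors and p53 targets were higher in 2 and lower in 9 of 19 cases (camera adjusted p = 0.0335, and adjusted p = 0.146 with an estimated correlation), BBC3 at -1.39, ZMAT3 at -1.21, CDKN1C at -1.14 and CDKN1A at -0.50. MYC and ribosome biogenesis genes were higher in 4 and lower in 11 of 23 cases (camera adjusted p = 0.0306, and adjusted p = 0.364 with an estimated correlation). The last pair of calls was lost without the second untreated control library (0.0546 for both), and that of MYC and ribosome biogenesis also without the first untreated SD3.23 library (0.0527).

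**Figure D4:**
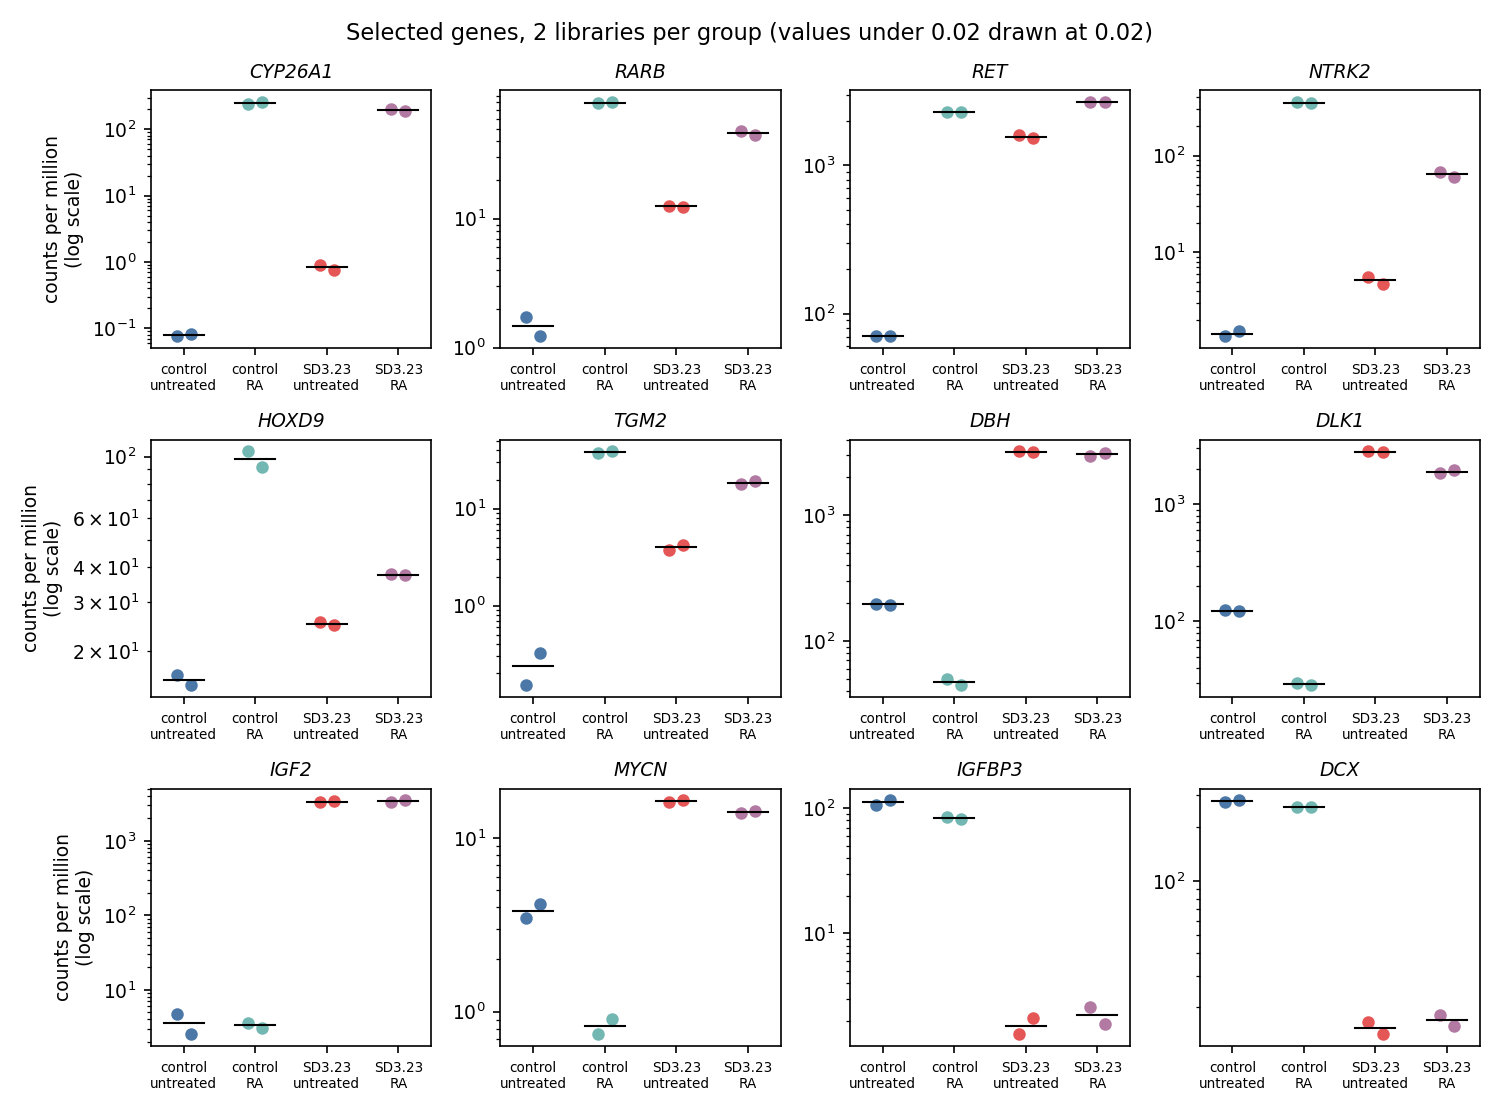
CPM, on a log10 axis, of 12 genes chosen after their values were seen, in each of the 8 libraries (points) with the group mean (line), for control and SD3.23 cells without and with RA. DBH stood at 195 CPM in untreated control and 3201 CPM in untreated SD3.23 cells.

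Not called by camera were the HOX and MEIS list (9 higher and 7 lower of 18, adjusted p = 0.411), Notch (6 and 4 of 17, 0.342), Wnt (7 and 5 of 14, 0.986) and Hedgehog (7 and 2 of 10, 0.0673). HOXD11 (3.21), HOXD10 (3.06) and HOXD13 (2.62) were higher and MEIS2 (-1.50) lower. LFNG (1.96), DNER (1.18) and NOTCH3 (0.84) were higher, and the Notch target HEYL had a ratio of 26.4-fold (95% counting interval 6.97 to 223). The Wnt inhibitor APCDD1 (6.19) was higher and LGR5 (-3.44), DKK1 (-1.74) and CCND1 (-1.69) were lower; the Hedgehog effectors GLI2 (4.20) and GLI1 (3.13) were higher. The IGF system had 7 higher and 4 lower of 15 (adjusted p = 0.463), with IGFBP3 at -5.89, and the matrix list 9 and 11 of 23 (0.463), with LAMA4 at 2.81 and COL11A1 at -2.46. Immediate early genes had 2 higher and 7 lower of 11 (adjusted p = 0.206), ATF3 at 2.35 against CYR61 at -3.32 and EGR1 at -1.43. Interferon genes had 11 higher and 2 lower of 16 (adjusted p = 0.0636), OAS1 at 2.19 and HLA-C at 1.18 against IFIT2 at -2.06. Schwann and glial markers had 3 higher and 2 lower of 7 (adjusted p = 0.986), PMEL at 2.91 against S100B at -2.23 and NGFR at -1.31. KRT19, a keratin, was higher (3.02), while EPCAM (-0.85) and CD14 (-0.26) did not pass. Mitochondrial genes took 4.45% and 3.75% of counts in the untreated control libraries and 2.88% and 3.08% in the untreated SD3.23 libraries, and with RA 3.98% and 4.02% in control and 3.09% and 3.54% in SD3.23.

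SD3.23 differed from control in 8520 genes without RA, 4477 higher and 4043 lower, with 1019 higher and 692 lower by at least 2-fold. Of the 10 lists called, 0 held with an estimated correlation, the lowest adjusted p being 0.0921. For the retinoid list the estimate was -0.0249, below the preset 0.01. Correlation between its members thus cannot account for the loss of that call. Adjusted over the list alone, 11 neuronal, 3 cell cycle inhibitor, 15 cholesterol and 4 Schwann genes were higher, 6 Wnt genes were lower, and the rest were as above. Median, mean and test differed in sign for the Wnt, matrix and Schwann lists. A test against a fold change of 1.5 called 1969 genes, and the assumed coefficient of variation left 4338.

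The same cells were then compared under RA. DLK1 stood at 29.2 ± 1.09 CPM in control and 1897 ± 68.3 CPM in SD3.23 cells (6.02 ± 0.05, adjusted p = 1.17e-99), and DBH at 46.9 ± 3.66 and 3047 ± 93.6 CPM (6.02 ± 0.05). MYCN stood at 0.826 ± 0.121 and 14.1 ± 0.269 CPM (4.09 ± 0.21), the log2 fold change of IGF2 was 9.96 and that of MYC -1.40. Several genes induced by RA in control cells were lower in SD3.23: NTRK2 (-2.46), JAG1 (-2.46), CYP26B1 (-2.36) and DKK2 (-3.31). Ranked by fitted value, which is uncertain where a group had 0 counts, the largest increases were CD177 with a ratio of 11206-fold (95% counting interval 2011 to 442674), LINC02382 (at least 607-fold), TMEM200A (at least 602-fold), PRUNE2 (at least 319-fold) and TRIM29 (11.78). The largest decreases were MAGEA6 by 866-fold (95% counting interval 155 to 34248), MAGEA3 by 485-fold (95% counting interval 134 to 4011), the receptor subunit GABRA3 by 180.3-fold (95% counting interval 49.6 to 1494), the adhesion molecule VCAM1 by 148-fold (95% counting interval 26.1 to 5877) and CSAG1 (-6.83).

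Adrenergic genes were higher in 18 and lower in 4 of 23 cases (camera adjusted p = 3.66e-12, and adjusted p = 0.0810 with an estimated correlation), CHGA at 4.76. DNA replication genes were higher in 25 of 25 cases (camera adjusted p = 8.84e-15, and adjusted p = 0.0791 with an estimated correlation), RRM2 at 1.22 and MCM3 at 0.99. Mitosis genes were higher in 25 and lower in 1 of 26 cases (camera adjusted p = 8.07e-13, and adjusted p = 0.157 with an estimated correlation), CCNA2 at 0.87. Cell cycle inhibitors and p53 targets were lower in 12 of 19 cases and higher in 0 (camera adjusted p = 3.79e-05, and adjusted p = 0.0791 with an estimated correlation), CDKN1C at -1.76, ZMAT3 at -1.33, CDKN1A at -1.15 and CDKN1B at -0.86. HOX and MEIS genes were higher in 4 and lower in 12 of 18 cases (camera adjusted p = 0.00265, and adjusted p = 0.107 with an estimated correlation), MEIS2 at -1.10 against HOXD13 at 2.09. Unfolded protein genes were higher in 10 and lower in 1 of 15 cases (camera adjusted p = 0.00773, and adjusted p = 0.127 with an estimated correlation), HSPA5 at 0.88, and cholesterol genes were higher in 13 and lower in 3 of 17 cases (camera adjusted p = 1.86e-04, and adjusted p = 0.166 with an estimated correlation), MVK at 1.27. Retinoid genes were higher in 7 and lower in 8 of 17 cases (adjusted p = 0.594), CRABP2 at 2.43.

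The other lists were not called. Mesenchymal markers had 8 higher and 4 lower of 14 (adjusted p = 0.209), VIM at 1.69 against NOTCH2 at -1.48, and neuronal genes 11 and 14 of 28 (0.217), NEFM at 1.23 and L1CAM at 1.19 against DCX at -3.90. Notch genes had 7 higher and 3 lower of 17 (adjusted p = 0.338), DNER at 2.40 and HEY1 at 1.21, Wnt targets 7 and 5 of 14 (0.639), APCDD1 at 7.48 against LGR5 at -2.18, and Hedgehog genes 7 and 3 of 10 (0.159), GLI2 at 4.87 and GLI1 at 3.61. MYC and ribosome biogenesis genes had 5 higher and 11 lower of 23 (adjusted p = 0.269), the IGF system 8 and 5 of 15 (0.245), with IGF1R at 1.04 and IGFBP3 at -5.19, and matrix genes 10 and 9 of 23 (0.716), with FN1 at -2.32 and LAMA4 at 1.72. Immediate early genes had 3 higher and 5 lower of 11 (adjusted p = 0.716), ATF3 at 3.38 and EGR1 at 1.33, interferon genes 8 and 3 of 16 (0.159), OAS1 at 4.24 and OAS3 at 2.62, and Schwann and glial markers 4 and 1 of 7 (0.217), PMEL at 3.79 and PMP22 at 1.02. KRT19 (3.64) was higher, EPCAM (-0.04) did not pass, and CD14 (1.34) passed, a call lost with DESeq2 (0.0949) and without the second SD3.23 library with RA (0.0534). Under RA 8956 genes differed, 4546 higher and 4410 lower, with 1133 higher and 799 lower by at least 2-fold. Of the 7 lists called, 0 held with an estimated correlation. The counts adjusted over the list alone differed only in 11 higher unfolded protein genes, and median, mean and test differed in sign for the retinoid, Notch, MYC and ribosome biogenesis, and immediate early lists. The test against a fold change of 1.5 called 2318 genes, and the assumed coefficient of variation left 4873.

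Genes on most of chromosome 18 were higher in SD3.23, a region chosen after its values were seen. Beyond 20 Mb, the 108 coding genes with a mean of at least 100 counts had a median log2 fold change of 0.54 without RA (quartiles 0.26 and 0.75) and 0.55 with RA, and 89 were called higher and 9 lower without RA. The 45 such genes up to 20 Mb had medians of -0.00 and 0.09, and the 10355 genes of other chromosomes 0.01 and -0.00. Leaving out chromosome 18, 8368 genes differed without RA and 8762 with RA.

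**Figure D5:**
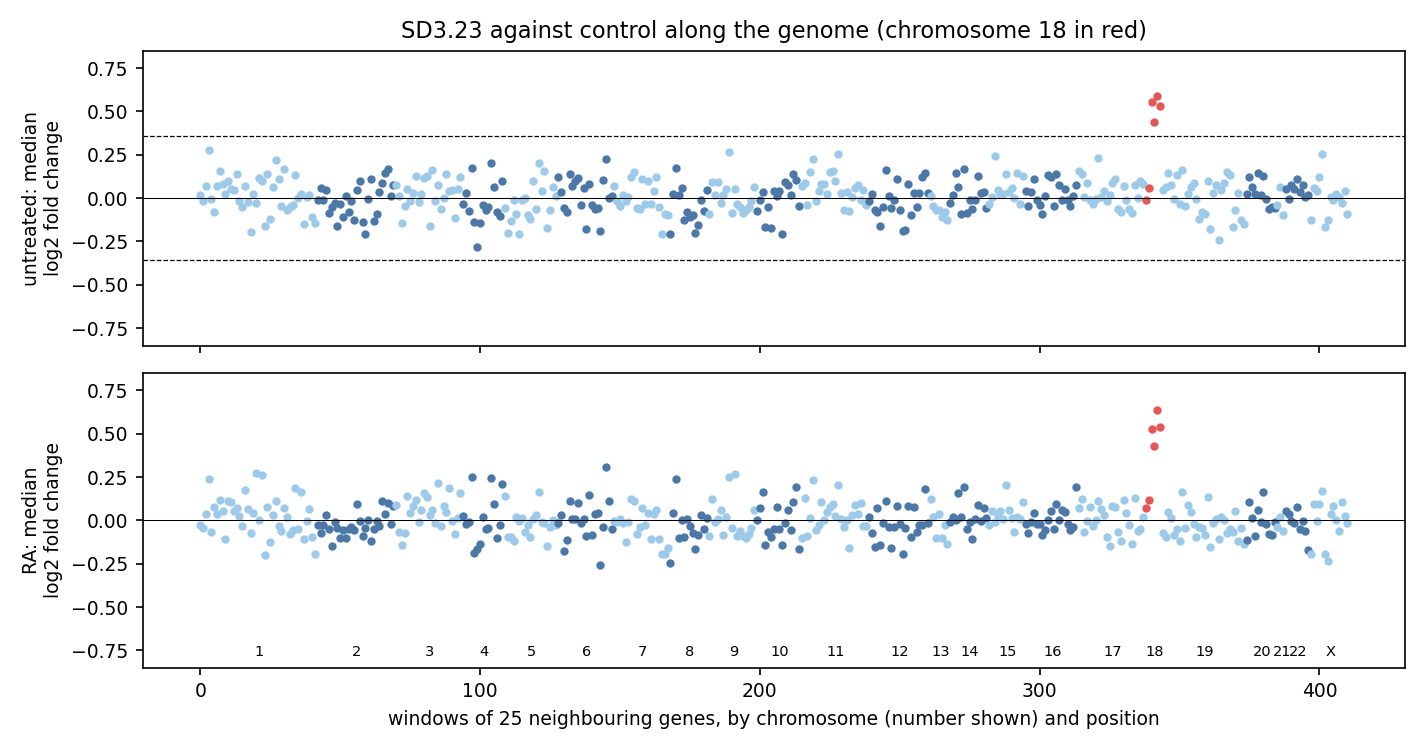
Median log2 fold change of SD3.23 against control, without and with RA, in consecutive windows of 25 coding genes (1 point each) in the order of the chromosomes. Chromosome 18 is in red, and 4 of its 6 windows lay past the limit of 0.358 from shuffled gene positions (dashed lines) without RA.

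The RA response of control cells and the untreated comparison of SD3.23 with control share the untreated control libraries, which ties their chance values together. Of the 2288 genes that RA raised in control cells, 1109 were also higher in untreated SD3.23, against 670 for independent lists, and of 2492 that RA lowered, 1189 were lower in SD3.23, against 659. The covariance of the log2 fold changes across genes was 0.151, against a mean of 0.0199 in 20 simulations with unchanged groups. The correlation (0.229 against 0.516) and the percent of genes with the same sign (59.4% against 67.0%) lay below those of the simulations. In the simulations both come from the shared libraries alone, and real changes in either comparison dilute them. Their lower values therefore cannot decide whether the comparisons agree. When each comparison used a different untreated control library, the covariance was 0.146 and 0.139, and the correlation was 0.199 and 0.190. Of the 775 genes raised by RA in control cells with a smaller response in SD3.23, 448 (57.8%) were higher in untreated SD3.23, against 661 of the other 1513 (43.7%). Genes lowered by RA went the other way: of the 734 with a smaller response in SD3.23, 309 (42.1%) were lower in untreated SD3.23, against 880 of the other 1758 (50.1%). These lists also share libraries. The difference between the responses equals the clone difference under RA minus the clone difference without RA. Choosing genes by it therefore partly sets their shares in untreated SD3.23, and neither difference of shares was tested.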

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

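All tests of explanations in this part were chosen after the results they address were seen; the tests of the difference between the RA responses were chosen before. Each result here was picked out because the RA response of SD3.23 differed from that of control cells in the test of that difference.

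MAML3 rose more with RA in SD3.23 than in control cells, by 1.23 on the log2 scale. The tables argue against a change of the whole region, since 12 tested neighbours within 2 Mb had a median difference of -0.037, and against reads of the overlapping MGST2, which fell with RA in SD3.23 (-0.38). An action of RA on transcription of MAML3 could account for a rise in both kinds of cell. MAML3 was also higher with RA in control cells (0.29, a call lost with the assumed coefficient of variation of 0.1). This smaller rise does not account for the larger rise in SD3.23, so it cannot decide the question. The value in control cells also does not separate the native gene from an introduced copy, if SD3.23 holds such a copy, because counts per gene pool both. The promoter of such a copy was not stated in the sources used here.

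In the gene-by-gene difference between the RA responses, the HOX and MEIS list (adjusted p = 6.89e-17) and the retinoid list (adjusted p = 9.36e-10) were lower in SD3.23. The mean RA response of the retinoid list was 3.07 in control and 1.85 in SD3.23 cells, but its median was larger in SD3.23 (0.69 and 1.21). Low counts in untreated control cells could inflate the control response. Bootstrap SDs here and below resample genes as if independent, although HOXD genes, for example, can share reads. They do not measure the spread between libraries. The 19 members with a mean of at least 100 counts in untreated control cells had a median difference of -0.60 (bootstrap SD 0.216), within the spread of the bound of -0.4 set for this test, so a part played by low counts stays open. Members might also start higher in the untreated clone and reach a similar level under RA. The 10 retinoid members with a smaller response had a median clone difference of 1.39 without and -0.57 with RA (bootstrap SD 0.295). The 14 HOX and MEIS members had 0.49 and -0.89 (bootstrap SD 0.485). A fall from the first to the second value is built into the choice of these members. Under RA, 8 retinoid members were called lower and 2 higher in SD3.23, and 9 and 4 of the HOX and MEIS members. The medians under RA were thus below the control level rather than at it. These calls set no minimum size, however, and both medians lay within the spread of the bound of -0.5 set for this test, so this stays open. A biological difference between the clone and control cells, through MAML3 or through any other change in the clone, also stays open and untested, since the design has 1 clone.

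Other genes whose responses differed were CRH at 3.98, CXCR4 at 3.75, PCDH10 at 3.05, TFPI2 at 2.97 and TMEM229A at 2.86. In the other direction were KIAA1244 at -6.25, CALCA at -6.15, TGM2 at -5.09, UBL4B at -4.99 and SNCAIP at -4.90. For UBL4B untreated control cells had 0 counts, and the call was lost without the first (0.0974) or second (0.0778) untreated control library.

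Further lists had more positive responses in SD3.23: adrenergic (adjusted p = 9.63e-07), DNA replication (adjusted p = 1.13e-08), Wnt targets (adjusted p = 4.06e-05), and the neuronal, IGF and Schwann lists (adjusted p = 0.00444 for each). More negative were the cell cycle inhibitors and p53 targets (adjusted p = 1.86e-06) and cholesterol synthesis (adjusted p = 0.00444). Of these lists, the cell cycle inhibitors alone held with an estimated correlation (adjusted p = 0.0345).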

How the results depend on the processing

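The assumed coefficient of variation and the run without chromosome 18 were chosen after the results were seen, and the other alternatives before. Counts of changed genes stayed within 1.5 times under limma voom, both other scalings, both other filters, fits of only the libraries compared and leaving out each library; with 1 library left in a group, that library was assumed to vary like the others. Leaving out 1 library gave 3630 to 4908 genes for RA in control, for RA in SD3.23 no more than 3991 and no fewer than 69.97% of the 4036 of the main fit (the largest drop of the 5 comparisons), 7366 to 8700 for untreated SD3.23, 7879 to 9052 for SD3.23 under RA, 1698 to 2062 for the difference between responses, 41 to 45 list calls, 1.52 to 1.67 for the untreated MAML3 difference and 0.77 to 0.84 for the size ratio of the RA responses. The size ratio was 0.768 over genes with an adjusted p under 0.01.

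DESeq2 called 2765 genes for RA in control cells, 1968 for RA in SD3.23 and 1061 for the difference; the cause was not tested. The test against a fold change of 1.5 called 732, 341, 1969, 2318 and 354 genes in the order used above, since it asks for a larger change. The assumed coefficient of variation called 1555, 828, 4338, 4873 and 541; it changes both the test and the spread, and their parts were not separated. Without chromosome 18, 8368 genes differed for untreated SD3.23 and 8762 under RA. The larger side of the split between higher and lower genes turned in several settings. With library size only it turned for RA in SD3.23 (1648 and 2458), SD3.23 under RA (4238 and 4746) and the difference (1053 and 1111). The filter on a mean of at least 1 CPM turned it for SD3.23 under RA (4281 and 4381) and RA in control cells (2356 and 2326). For RA in control cells DESeq2 (1408 and 1357) and the test against a fold change of 1.5 (441 and 291) turned it too. So did the assumed coefficient of variation (824 and 731), only the 4 libraries compared (2514 and 2362) and leaving out the second SD3.23 library with RA.

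Of 44 list calls, 8 held with an estimated correlation. That setting also has fewer degrees of freedom, so the losses are not due to correlation alone. The directional fry test called 74 of 95 and its mixed test 95, and neither compares a list with other genes; fry turned the direction of the neuronal list in the difference between responses (adjusted p = 0.509), where camera gave 0.00199 to 0.0185 on leaving out 1 library. Named genes gave 7634 comparisons that kept their direction and side of the threshold, 332 that lost the call, 2 that gained it and 11 that turned direction. Of those that turned, MAML1 and MAML2 were not called in the main fit, and PMEL for RA in SD3.23 was (0.46, adjusted p = 0.0322). MAML2 for RA in control cells was -0.016 with library size only. On leaving out 1 library, MAML1 for RA in control ran from -0.091 to 0.024, MAML2 from -0.15 to 0.19 for RA in control, -0.13 to 0.30 for RA in SD3.23 and -0.14 to 0.29 for the difference, and PMEL for RA in SD3.23 from -0.069 to 0.91.

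With the replicate number as a replicate block, 4713, 3961, 8463, 8885 and 2155 genes were called. The residuals gave no sign that replicate numbers pair the libraries, without excluding it, so this is given only as a check.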

Other observations

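The groups, regions and tests in this part were chosen after the data were seen, except the test on GC content and length, whose result had not been seen. The imprinted and X-linked groups were picked while other families (semaphorins and plexins, neurotransmitter receptors, protocadherins, MAGE genes) were also looked through, so they carry no list test.

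Of 14 tested genes known as imprinted (expressed from 1 parental copy), 9 were higher and 2 lower in SD3.23 than in control cells without RA, a comparison in which 55.7% of all tested genes differed. Besides IGF2 and DLK1, RTL1, which shares the DLK1 locus, stood at 12.02 ± 1.46 CPM in control and 258 ± 9.38 CPM in SD3.23 cells (4.42 ± 0.07). H19, the noncoding RNA beside IGF2, stood at 0.398 ± 0.243 and 4.79 ± 0.817 CPM (3.57 ± 0.35). NNAT (1.57 ± 0.05) and the growth regulator PLAGL1 (1.31 ± 0.08) were also higher, and CDKN1C (-1.14 ± 0.10) and SNRPN (-0.62 ± 0.16) were lower. PEG10 (0.13) and SGCE (0.31) differed by little, and MEST (-0.43), ZIM2 (-0.02) and KCNQ1OT1 (-0.03) did not pass the test.

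On chromosome X, neighbouring genes from MAGEA5 (ENSG00000242520, chromosome X, 151282526 to 151306993) to PNMA3 (ENSG00000183837, chromosome X, 152224766 to 152228827) were mostly lower in SD3.23. Of 15 tested in untreated cells, 2 were higher and 11 lower. GABRA3, a subunit of a neurotransmitter receptor, went from 12.1 ± 0.732 to 0.136 ± 0.192 CPM between control and SD3.23 cells (-6.26 ± 0.32), PNMA3 from 7.67 ± 0.251 to 0.315 ± 0.254 CPM (-4.64 ± 0.32), and MAGEA10 from 179.7 ± 1.82 to 144 ± 6.46 CPM (-0.32 ± 0.04). NSDHL (0.61 ± 0.07) and CETN2 (0.30 ± 0.07) of the same stretch were higher. MAGEA genes of this stretch are similar in sequence, so their separate values are uncertain.

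Genes on chromosome 18 beyond 20 Mb were higher in SD3.23, and the hypothesis weighed was that the clone carries extra copies of most of this chromosome. Bias by GC content or transcript length is argued against, since the median in untreated cells was 0.54 before and 0.58 (bootstrap SD 0.0293) after that trend was taken off. Extra copies remain possible by these values: 3 copies against 2 would give 0.58, and the RA libraries gave a median of 0.55. RA moved the same genes by medians of -0.03 in control and 0.03 in SD3.23 cells. The RA libraries come from the same clone and library series, so they would repeat any lasting difference and are no separate evidence for copies. In 411 windows of 25 genes, the 4 beyond the limit of 1000 shuffles (0.358) in untreated cells were all on chromosome 18. For RA in control cells 1 window, at 0.405, also lay beyond its own limit (0.189), so a window can pass without a difference between the kinds of cell. Copy number was not measured here, and a library batch cannot be told apart from the kind of cell, so the hypothesis stays open.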
